A study of Mus musculus with 2 samples.

How the data were processed

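Gene expression was measured on 2 Affymetrix HT MG-430 PM arrays, which carry sets of short probes for mouse transcripts. Per the labels, the RNA came from CD4 T cells of 6-week-old C57BL/6 mice that carry a Foxp3-eGFP reporter, in which regulatory T cells are green. Naive Foxp3-negative CD4 T cells were sorted and activated for 48 hours with soluble anti-CD3 antibody, which triggers the T cell receptor. Splenocytes without T cells served as antigen-presenting cells (APC) and had been treated with mitomycin C at 50 ug/ml, which stops their division. They came either from wild type (Wt) mice or from mice with an OX40L transgene (OX40L-Tg). Living CD4 T cells were then sorted again. There is 1 array for each kind of APC. The extraction protocol in the labels speaks of adipose tissue, whereas the sample labels and the series' design text speak of CD4 T cells. Adipocyte transcripts were therefore checked and are given with the cell type markers.

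The deposited values are probe set intensities on a linear scale, made by the authors with RMA per the submitters' processing notes. RMA corrects the background, equalises the distributions of the arrays and combines the probes of a set. Its version is not given in the sources used here, nor is the set of arrays that was normalized together. A log2 scale had been assumed before the data were examined. The values ran from 4.69 to 14686 units, so log2 was taken first, which the plan had foreseen for linear values. RMA shrinks low intensities together, so a difference between a low and a high value is understated, and an intensity near background shows no presence of a transcript. Because the arrays were equalised, a change of total RNA per cell leaves no trace in these values.

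The table holds 45141 probe sets. Of these, 28898 were paired with 1 gene symbol by the platform annotation, 551 with several, and 15692 were not listed and are unnamed here. For 28689 of the 28898, the Entrez number was found in the RefSeq gene table of the mouse assembly GRCm38.p6, which changed 0 symbols. That table was used for names and for which genes neighbour each other. Probe sets with several symbols named no gene. A gene took the value of its probe set with the highest mean over both arrays, which gave 17097 genes. The floor was each array's median over all probe sets, 3.88 on the log2 scale for both, and a gene counted as above the floor if its value reached it on at least 1 array. Differences are OX40L-Tg APC minus Wt APC on the log2 scale, and a size of 2-fold was the threshold.

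With 1 array per group there is no test, standard error or p-value, and nothing measures the spread between cultures or mice. The number of arrays limits the precision. Technical scatter could be judged only from probe sets of the same gene and from array controls. For each of 27 pathway lists and 18 cell type or control lists fixed before the data were examined, the median difference of the members above the floor was compared with 10000 random lists of the same size, matched on mean level in 20 bins. A list is described as shifted when its median lay below the 2.5th or above the 97.5th percentile of those random lists. Lists with under 5 members above the floor have no percentile. These percentiles describe these 2 arrays and are not p-values. Of 751 list genes with a value, 57 stood on 2 or more lists, and members of a list are not independent replicates. Of 866 list genes, 114 had no value and are not analysed here.

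Genes were named by a rule fixed before the data were examined. It took the 10 genes with the largest difference in each direction whose probe sets above the floor all had the same sign, a set of key T helper and OX40 pathway genes, and up to 4 members of each list with the largest difference. Ccr4, Ccr8, Ecm1, Id3, Gzmb, Il12rb1, Hspa5, Adipoq and Fabp4 are list members outside that rule, named after their values were seen. Among the genes of at least 2-fold, 10 unnamed gene models and 6 genes with disagreeing probe sets were left out of the largest 10. The background level was the 95th percentile of the genes restricted to other organs, 31.6 units on the Wt APC array and 33.8 units on the OX40L-Tg APC array. Where 1 of the 2 values of a named gene was below it, the fold is given as a lower bound against that level, a use chosen after seeing the data.

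The calculations were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 (lowess, span 0.3) and matplotlib 3.10.9. They were tested on simulated arrays of 10505 genes made from the Wt APC against OX40L-Tg APC comparison, with a scatter chosen for the simulation. That scatter was equal at every level and smaller than the SD of 0.39 of the differences between the real arrays. The simulation therefore gives no rate of false calls in the data. In that simulation 100% of changes of 1.5 and of 2 on the log2 scale passed 2-fold, 0 unchanged genes did, 5.67% of 300 unchanged lists were described as shifted, and so were 100% of 50 lists moved by 0.3. Alternatives tried were the mean of all probe sets of a gene, leaving out probe sets marked as shared between transcripts, other floors, 3 other scalings, an offset of 32 units, thresholds of 1.5-fold and 3-fold, and other summaries of the lists and random lists.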

Results

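The series asks how the OX40 ligand (OX40L) on antigen-presenting cells (APC) alters the transcripts of CD4 T cells during their first activation. OX40, encoded by Tnfrsf4, is a costimulatory receptor of activated T cells, and Tnfsf4 encodes its ligand. Naive Foxp3-negative mouse CD4 T cells were activated for 48 hours with anti-CD3 antibody and splenic APC that were either wild type or carried an OX40L transgene, and were sorted again before RNA was taken. There was 1 array for each condition, so no value has a replicate and no difference can be tested. Intensities had medians of 14.7 units on both arrays, and the arrays correlated with r = 0.993 over all 45141 probe sets. Of 17097 genes with a value, 10541 were above the floor and 8529 were above the background level set by genes of other organs. Paired values are given with Wt APC first, and differences are OX40L-Tg APC minus Wt APC on the log2 scale.

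T cells activated with OX40L-Tg APC read far higher for transcripts of the type 2 and Th9-associated cytokines. Il24, Il21, Il9, Il4 and Il13 were among the 10 genes with the largest positive difference. Transcripts induced by interferon-gamma, several markers of resting T cells and the proapoptotic gene Bcl2l11 were lower. In all, 164 genes were at least 2-fold higher and 123 at least 2-fold lower with OX40L-Tg APC, which together is 2.72% of the genes above the floor. Between the arrays 92.8% of genes differed by less than 1.5-fold, and the median difference was 0.02. OX40 itself was abundant in both conditions, at 5650.0 units with Wt APC and 6262 units with OX40L-Tg APC. Tnfsf4 read 154 and 128 units, a difference of -0.26.

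Il24, which encodes a cytokine of the IL-10 family, read 22.7 units with Wt APC, below background, and 1306 units with OX40L-Tg APC, at least 41.4-fold higher. Il21, a cytokine of follicular helper and other effector T cells, read 25.6 and 1413 units, at least 44.8-fold higher, with differences of 3.39 and 5.79 in its 2 probe sets. Gzma, the serine protease granzyme A, was 29.3-fold higher at 3048 units. Lilrb4a, an inhibitory receptor of the immunoglobulin superfamily, was 17.7-fold higher at 1802 units. Its value rests on 1 probe set marked as shared between transcripts, so the signal may not be of this gene alone. Akr1c18, a hydroxysteroid dehydrogenase that inactivates progesterone, was 9.39-fold higher. Ermn, known as a cytoskeletal protein of oligodendrocytes, read 22.5 and 399 units. Il12a, the p35 subunit shared by IL-12 and IL-35, read 17.4 and 173 units, with the Wt APC value below background for both of these genes.

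Among the genes with the largest negative differences, Ccdc141 read 195 units with Wt APC and 10.8 units with OX40L-Tg APC, at least 5.76-fold lower, but its 4 probe sets ranged from -4.17 to -0.99. Klrk1, which encodes the activating receptor NKG2D, was at least 4.75-fold lower. Calhm6, a channel family gene, was at least 6.80-fold lower, and Ifit1bl1, of the interferon-induced Ifit family, at least 2.73-fold lower. Txk, a Tec family kinase downstream of the T cell receptor, was 7.38-fold lower. Klf2, a transcription factor that keeps T cells quiescent and directs their homing, was 5.51-fold lower at 65.0 units. Nrn1 and Nsg2, both first known from neurons, were 7.24-fold and 6.07-fold lower. Ms4a4b, a membrane protein of the Ms4a family, read 3489.6 and 645 units, with a difference of -0.47 in its other probe set. Hba-a1, an alpha globin gene, was 5.60-fold lower and is taken up with the erythroid markers.

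**Figure D1:**
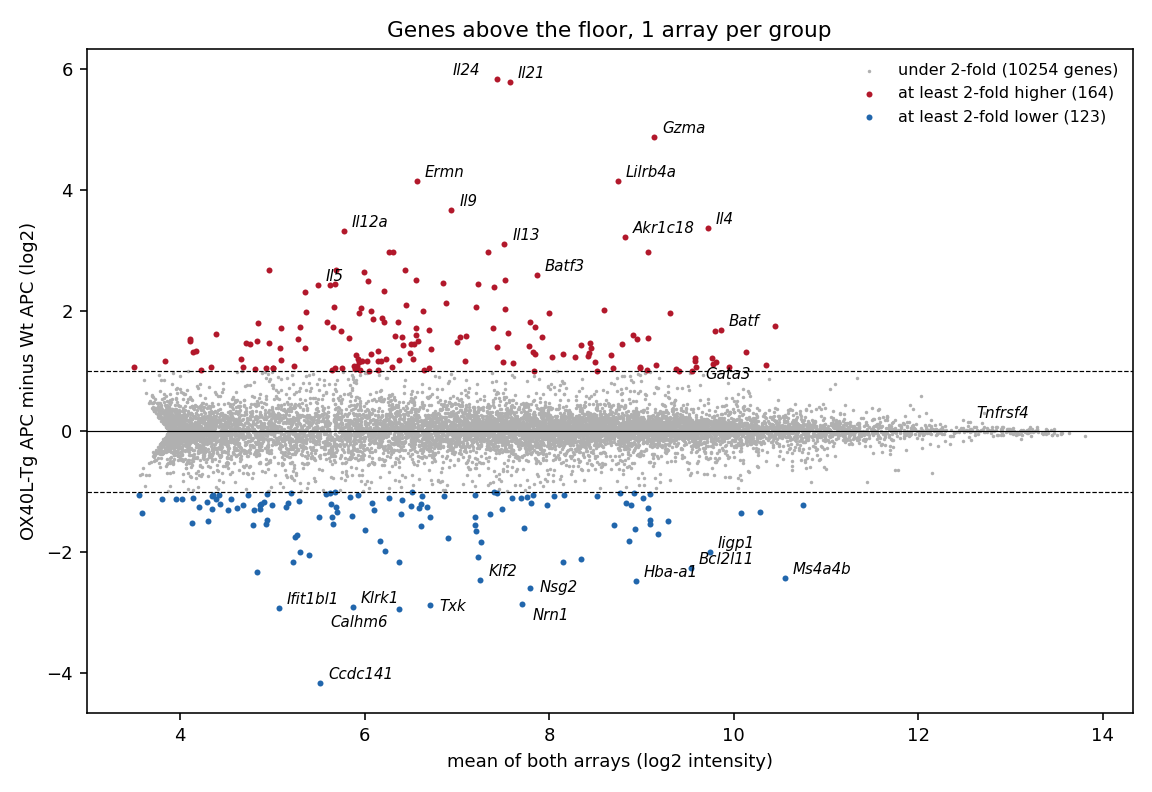
Each point is a gene above the floor, with the mean log2 intensity of both arrays on the x axis and the log2 difference, OX40L-Tg APC minus Wt APC, on the y axis; dashed lines mark 2-fold. The 164 genes at least 2-fold higher reach 5.84 at Il24, and the 123 genes at least 2-fold lower reach -4.17 at Ccdc141. Both of these genes have 1 value below background, so their differences stand for at least 41.4-fold and at least 5.76-fold. Tnfrsf4 lies at 0.15.

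Cytokines and regulators of type 2 helper T cells showed the largest shift of any list in the main setting. Of 15 Th2 genes above the floor, 11 were at least 2-fold higher with OX40L-Tg APC and 0 were at least 2-fold lower, with a median difference of 1.22. That median lay above all 10000 random lists of the same size and level. Il4, the cytokine that drives type 2 differentiation, read 262 units with Wt APC and 2711 units with OX40L-Tg APC, 10.4-fold higher. Il13, which acts on epithelium and macrophages, was 8.62-fold higher, and Il5, the growth factor of eosinophils, at least 3.31-fold higher. Gata3, the transcription factor that specifies the Th2 state, read 512 and 1145 units, a 2.24-fold difference. The chemokine receptors Ccr4 and Ccr8 differed by 1.57 and 1.11, and Ecm1, a matrix protein needed for Th2 cell exit from lymph nodes, by 1.97. Pparg passed 2-fold as well, but both of its values were below background. In the same samples MHC class II transcripts, typical of APC, were higher, with a median difference of 0.41, and T cell markers were lower, with a median of -0.25.

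Genes associated with IL-9-producing T cells were also higher as a group. Of 18 above the floor, 7 were at least 2-fold higher and 0 at least 2-fold lower, and the median of 0.39 lay above all 10000 random lists. On the same arrays MHC class II genes were higher by a median of 0.41, dendritic cell markers, a list that shares Batf3 and Ccl17 with this one, by 0.35 and B cell markers by 0.23. Il9 read 34.4 units with Wt APC, just above background, and 437 units with OX40L-Tg APC, 12.7-fold higher. The AP-1 factors Batf3 and Batf, which work with Irf4 at cytokine genes, were 6.04-fold and 3.21-fold higher, whereas Irf4 differed by 0.37. Il10, an anti-inflammatory cytokine, was 3.53-fold higher. Relb, the noncanonical NF-kB subunit, read 147 and 150.0 units. Id3, an inhibitor of E proteins, differed by -0.91. Gata3 and Stat6 stand on both this list and the Th2 list. Excluding genes below the background level on both arrays moved the median to 0.90 and that of the Th2 list to 1.60. Genes low on 1 array only, such as Il21 here and Il24 and Il5 on the Th2 list, were kept. That rule favours members with large differences.

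**Figure D2:**
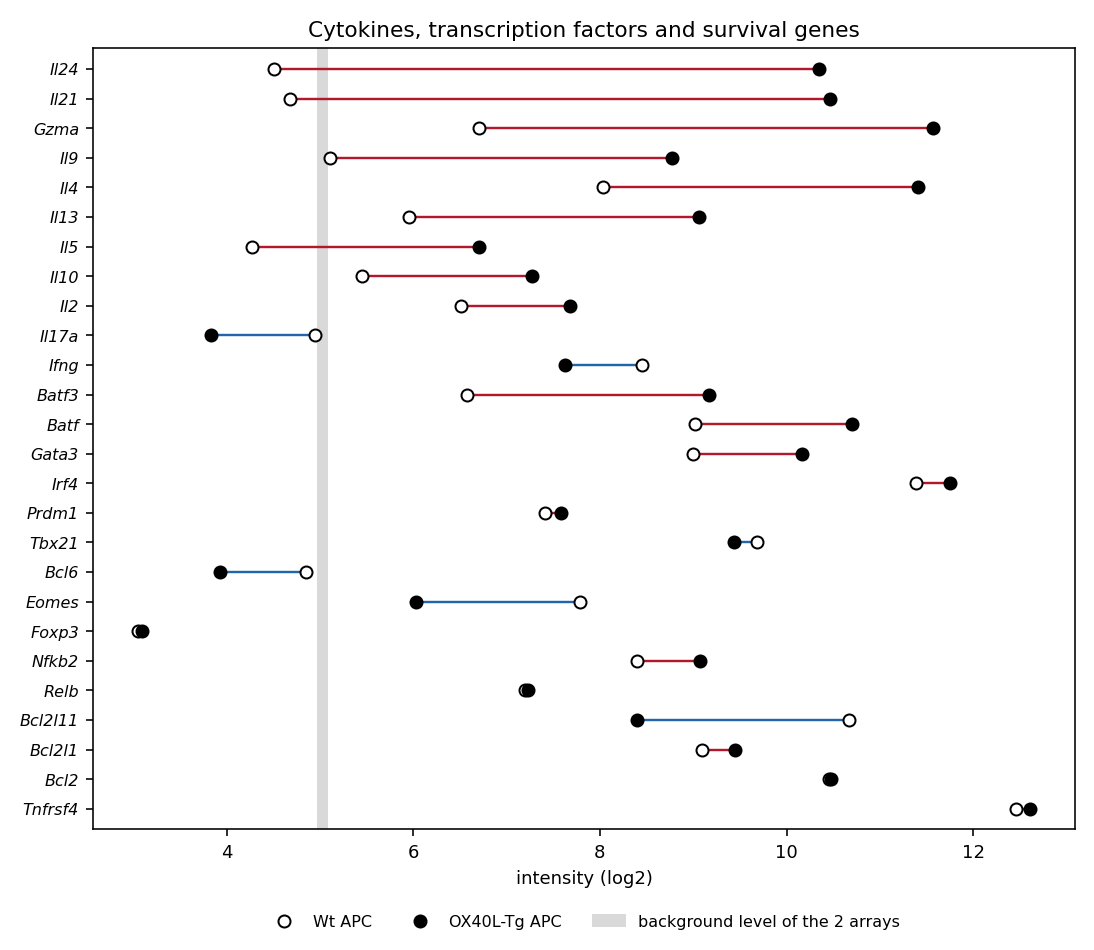
Log2 intensity on the x axis of cytokine, transcription factor and survival genes with Wt APC (open circles) and OX40L-Tg APC (filled circles), 1 array each, with the background level shaded. With Wt APC, Il24, Il21 and Il5 lie below background, and with OX40L-Tg APC they lie at 10.35, 10.46 and 6.70, while Foxp3 lies at 3.04 and 3.09.

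Genes of the NF-kB pathway, which OX40 is known to engage through TRAF adaptors, were modestly higher. Of 26 above the floor, 23 had the higher value with OX40L-Tg APC, 5 by at least 1.5-fold, and the median of 0.31 lay above all 10000 random lists. B cell and MHC class II genes, whose cells also use this pathway, were higher by medians of 0.23 and 0.41 on the same arrays. Tnfaip3, the deubiquitinase A20 that restrains NF-kB, was 2.16-fold higher. Cd83, Map3k8 and Nfkb2 differed by 0.80, 0.69 and 0.68, and Traf1, a TRAF adaptor, by 0.56. Ikbke, an IkB kinase-related gene, differed by -0.75. Activation genes had a median of 0.24, above all random lists, with 4 of 24 at least 2-fold higher and 2 at least 2-fold lower. Egr2, a transcription factor induced by the T cell receptor, was 2.71-fold higher. Fosl2, an AP-1 subunit, was 2.60-fold higher, with a difference of 0.84 in its other probe set. Nr4a3, an orphan nuclear receptor also induced by receptor signalling, was 2.53-fold lower, but its 3 probe sets ranged from -1.34 to -0.24. Il2, the T cell growth factor, read 90.9 and 205 units, and Il2ra, its high-affinity receptor chain, 1896 and 3512 units.

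Cytokine receptors and STAT feedback genes had a median of 0.12 at percentile 99.5 of random lists. Their mean was 0.13, at percentile 94.1, which no longer sets the list apart. Jak2, a receptor-associated kinase, was 2.21-fold higher, Socs2 and Socs3, feedback inhibitors of STAT signalling, differed by 0.97 and 0.94, and Il6st, the shared gp130 chain, by -0.89. Receptors and ligands of the TNF superfamily, to which OX40 belongs, were not shifted as a group, with a median of 0.10 at percentile 96.0. The direction depended on the processing, with a median of -0.26, below all random lists, when the floor was set at the 75th percentile, one of 0.09 at percentile 98.2 after a lowess correction, and a mean of -0.02. Tnfrsf8, which encodes CD30, was at least 1.16-fold higher at 36.6 units, and Tnfrsf9, which encodes the costimulator 4-1BB, differed by 0.18. Cd27, another costimulator of the family, was 2.06-fold lower, Tnfsf10, which encodes TRAIL, was at least 1.72-fold lower, and Tnfsf11, which encodes RANKL, differed by -0.97.

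Transcripts induced by interferon-gamma were lower as a group. Of 17 above the floor, 6 were at least 2-fold lower, 0 were at least 1.5-fold higher, and the median of -0.69 lay below all 10000 random lists. Iigp1, an immunity-related GTPase that attacks pathogen vacuoles, read 1704 units with Wt APC and 428 units with OX40L-Tg APC. Gbp7, a guanylate-binding protein, was 2.75-fold lower, and the chemokines Cxcl10 and Cxcl9 were 2.65-fold and 2.35-fold lower. Genes of the type I interferon response were not shifted, with a median of -0.08 at percentile 6.00, but were lower under both stricter floors, at -0.20 and -0.26. Of 24 members, 3 were at least 2-fold lower and 1 at least 2-fold higher. Ifit2 was 2.45-fold lower, Cmpk2 and Ifit1 were at least 1.16-fold and 1.14-fold lower against the background level, and Oas1g, an antiviral oligoadenylate synthase, was 2.71-fold higher. MHC class II transcripts, many of them inducible by interferon-gamma in APC, were higher by a median of 0.41 in the same comparison.

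Th1 and cytotoxic genes were lower by the median, at -0.27, below all 10000 random lists, with 16 of 22 members lower. T cell markers were lower by a similar median of -0.25 on the same arrays. Ifng, the defining Th1 cytokine, read 351 and 198 units, a 1.77-fold difference. Eomes, a T-box factor of cytotoxic and memory T cells, was 3.40-fold lower, and Cxcr3, a chemokine receptor of Th1 cells, 1.92-fold lower. Tbx21, which encodes the Th1 factor T-bet, differed by -0.25. The 6 higher members included Gzma at 4.87 and Il12rb1, an IL-12 receptor chain, at 0.60, whereas Gzmb, the related granzyme B, was abundant on both arrays at 6382 and 5782 units. With the mean in place of the median, the list stood at -0.05 and at percentile 17.9, which does not set it apart.

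Th17 genes were not shifted, with a median of 0.00 at percentile 44.3, and their members diverged. With the floor at the 75th percentile the median was 0.69 at percentile 99.5, which sets the list apart as higher. Il17a, the defining cytokine, read 30.8 and 14.2 units, both below background. Ccr6, a Th17 chemokine receptor, was at least 1.44-fold lower, whereas Ahr, a ligand-activated factor that promotes IL-22 expression, was at least 7.04-fold higher, with a difference of 0.00 in its other probe set. Treg genes had a median of 0.13 at percentile 98.1, and at percentile 96.5 among random lists not matched on level. Foxp3, the factor that defines regulatory T cells, read 8.25 and 8.50 units, both below background. Ikzf4, a Foxp3 partner, was 2.03-fold higher, with a difference of 0.28 in its other probe set, and Ctla4, an inhibitory receptor, differed by -0.34. Tfh genes had a median of -0.08 at percentile 5.36 and a mean of 0.54 at percentile 99.75, so the list is apart by the mean and not by the median. Il21, its highest member above the floor at 5.79, weighs heavily on that mean, and the mean without it was not computed. Pou2af1, a B and T cell coactivator, was 5.25-fold higher and Cd200 2.33-fold higher, whereas Slamf6, an adhesion receptor of T and B cells, was 3.14-fold lower and the defining factor Bcl6 was below background on both arrays.

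Genes of naive and quiescent T cells were lower, with 12 of 15 below their Wt APC value, a median of -0.24 and a percentile of 0.01. T cell markers were lower as well, by a median of -0.25. Foxp1, a factor that holds T cells in quiescence, was 2.89-fold lower, with 7 probe sets between -1.61 and -1.04. Klf3 and Bach2, a repressor that limits effector differentiation, differed by -0.89 and -0.72. Coinhibitory receptors and costimulators had a median of -0.32, below all random lists, but a mean of -0.02 at percentile 31.4. Vsir, which encodes the checkpoint protein VISTA, was 2.00-fold lower and Cd80 differed by -0.73, while the inhibitory receptor gene Cd200r1 was at least 1.52-fold higher. Anergy genes had a median of -0.26 at percentile 0.02 and a mean of -0.11 at percentile 9.40. Cblb, a ubiquitin ligase that raises the threshold of activation, and Dgkz, a kinase that removes diacylglycerol, differed by -0.65 and -0.60, and Nfatc1 by -0.90, whereas Egr2, also on this list, differed by 1.44 and was its only member past 2-fold.

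Apoptosis regulators were not shifted as a group, with a median of 0.06 at percentile 78.4, yet held a large single difference. Bcl2l11, which encodes the proapoptotic protein Bim, read 1631 units with Wt APC and 338 units with OX40L-Tg APC, 4.83-fold lower, and its 5 probe sets lay between -2.35 and -2.16. The antiapoptotic genes Bcl2 and Bcl2l1 differed by 0.01 and 0.35, and Birc5, which encodes survivin, by -0.10. Cflar, an inhibitor of death receptor signalling, was 1.67-fold higher. Targets of p53 had a median of 0.26, above all random lists, and a mean of 0.21 at percentile 95.7. Cdkn1a, the cell cycle inhibitor p21, was 2.14-fold higher and Plk2, a stress-induced kinase, 2.73-fold higher, while Trp53inp1, which promotes p53-dependent death and autophagy, was 2.40-fold lower.

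Genes of the unfolded protein response and of amino acid shortage were higher. Of 22 above the floor, 4 were at least 2-fold higher and 0 at least 2-fold lower, and the median of 0.36 lay above all 10000 random lists. On the same arrays MHC class II genes were higher by a median of 0.41, dendritic cell markers by 0.35 and B cell markers by 0.23, and T cell markers were lower by -0.25. Cth, which makes cysteine from cystathionine, was 5.04-fold higher, and Chac1, which degrades glutathione, 4.27-fold higher. Trib3, a pseudokinase induced by ATF4, and Asns, asparagine synthetase, were 2.23-fold and 2.05-fold higher. These 4 genes are known targets of ATF4. The endoplasmic reticulum chaperone Hspa5 differed by 0.25 and Xbp1 by -0.11. Heat shock genes had a median of 0.00 at percentile 40.5, with Hsph1 at 0.34.

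Genes of growth and proliferation differed by little. Ribosome biogenesis and Myc target genes were higher in 26 of 27 members, with a median of 0.17 above all random lists, but 0 passed 1.5-fold. Rrp12 and Nop2, both ribosome assembly factors, differed by 0.43 and 0.37. All 44 cell cycle genes were within 1.5-fold, with a median of -0.03 at percentile 1.17 and a mean of -0.02 at percentile 14.9. E2f2 and Mybl2, both proliferation factors, differed by -0.48 and 0.39. Sterol synthesis genes were lower in 16 of 19 members, with a median of -0.16 at percentile 0.03, and Dhcr7, a late enzyme of cholesterol synthesis, differed by -0.55. Glycolysis and hypoxia genes had a median of -0.05 at percentile 0.88 and a mean of -0.04 at percentile 14.7. Hk2, which encodes hexokinase, differed by 0.46, and Aldoc, an aldolase, by -0.71. Oxidative phosphorylation genes had a median of 0.00 at percentile 29.0, and all 25 were within 1.5-fold.

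Regulators of chromatin stood close together on the arrays. Repressive chromatin modifiers had a median of -0.05 at percentile 3.78, with 26 of 27 within 1.5-fold, and were apart as lower under 3 of the alternative settings. The polycomb methyltransferase gene Ezh2 differed by 0.01, the DNA methyltransferase gene Dnmt3a by -0.38 and the deacetylase gene Sirt1 by -0.13. Enhancer coactivators and acetyltransferases had a median of 0.04 at percentile 60.6, and all 25 were within 1.5-fold. Ncoa2 and Crebbp, both coactivators, differed by -0.47 and -0.33. TGF-beta signalling genes, relevant because TGF-beta is used to induce Th9 cells, had a median of -0.01 at percentile 30.0. The receptor gene Tgfbr2 and the signal transducer Smad3 differed by -0.30 and -0.23, and their probe sets differed in sign.

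Markers of other cells were checked because the T cells were sorted from cultures with splenic APC. No list median in the report was adjusted for these markers. MHC class II genes were higher with OX40L-Tg APC in 8 of 9 cases, with a median of 0.41 at percentile 99.98; Cd74, the invariant chain, read 901 and 1346 units. B cell markers had a median of 0.23 at percentile 98.7, with Cd79b, a B cell receptor subunit, at 166 and 313 units and Fcer2a at 259 and 520.0 units. Dendritic cell markers had a median of 0.35 at percentile 99.9, led by Batf3 and by Ccl17, which was 2.72-fold higher; activated T cells can express both. T cell markers were lower in 12 of 14 cases, with a median of -0.25 below all random lists, and Cd3e and Cd3g, subunits of the T cell receptor complex, differed by -0.67 and -0.62. Erythroid markers had a median of -0.39 at percentile 0.14, with Hba-a1 at 1161 and 207 units in a probe set marked as shared. Macrophage markers had a median of 0.14 at percentile 86.5 and stayed near background.

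NK cell markers were not shifted, with a median of -0.06 at percentile 22.3. Excluding genes below the background level on both arrays moved the median to -1.77, below all random lists. Of 8 members above the floor, 4 were higher and 4 lower. Klrd1, which encodes CD94, and Klrk1 were at least 2.33-fold and 4.75-fold lower, whereas Gzma, also on this list, differed by 4.87. The CD8 T cell genes Cd8a and Cd8b1 differed by 0.17 and 0.32, the plasma cell genes Derl3 and Xbp1 by 0.24 and -0.11, with Cd8a and Derl3 below background on both arrays. Medians of the other lists with under 5 members above the floor were -0.15 for gamma-delta T cells, -0.34 for neutrophils, -0.58 for mast cells and basophils, -0.31 for platelets and -0.03 for stromal and endothelial cells. In that last list Pecam1, an adhesion molecule also found on naive T cells, was 3.12-fold lower. Adipocyte genes were near background, with Adipoq at 8.89 and 8.31 units and Fabp4 at 8.88 and 8.66 units, and a median difference of 0.09 at percentile 77.3. Genes of other organs had a median of 0.07 and housekeeping genes of 0.01. Xist, which female cells express from the inactive X chromosome, was at least 6.81-fold higher with OX40L-Tg APC, at 215 units, and the Y-linked genes Kdm5d, Uty and Eif2s3y differed by -0.48, -0.31 and -0.19, so the list of sex-linked genes had a median of -0.25.

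**Figure D3:**
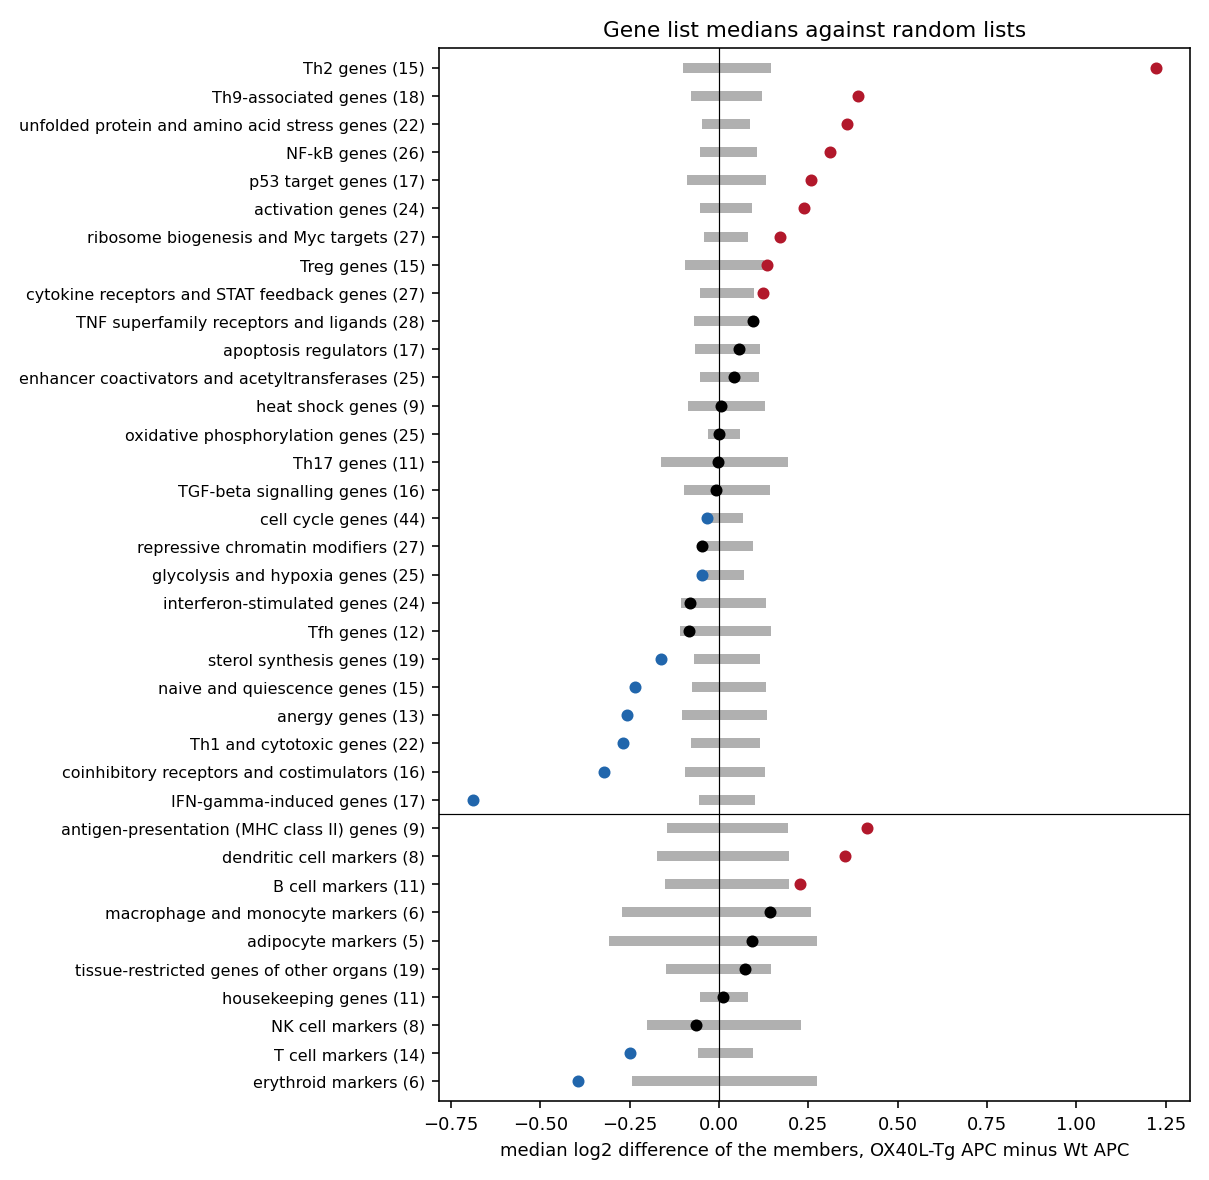
Points are the median log2 differences (x axis, OX40L-Tg APC minus Wt APC) of 37 gene lists, with the number of members above the floor in brackets, and grey bars span the central 95% of 10000 random lists; red points lie above and blue points below that range. Th2 genes stand farthest right at 1.22 and interferon-gamma-induced genes farthest left at -0.69, and lists under the horizontal line are cell type and control lists.

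Technical scatter could be judged from genes with several probe sets and from array controls. Of 4195 genes with 2 or more probe sets above the floor, 63.5% had all of them in 1 direction, and the median SD between probe sets was 0.0975. Among genes of at least 2-fold, 90 of 96 had all probe sets in 1 direction. These genes were chosen by the difference of 1 of the same probe sets, which favours agreement. Probe sets of a gene read the same hybridisation, so their agreement leaves out the spread between hybridisations, cultures and animals. Of the 164 genes at least 2-fold higher, 48 had a Wt APC value under the background level, and of the 123 at least 2-fold lower, 52 had an OX40L-Tg APC value under it. The 3' and 5' probe sets of actin differed by 0.31 with Wt APC and 0.34 with OX40L-Tg APC, and those of Gapdh by 0.04 and 0.08. The ends of these transcripts were thus read alike on both arrays. Labelling controls, bacterial transcripts added before labelling, were higher with OX40L-Tg APC in all 24 probe sets, by a median of 0.57. Hybridisation controls, added after labelling, had a median of 0.10.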

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

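Both results here were looked at only after the comparison had been made, and neither has a replicate. The labelling controls are bacterial poly-A transcripts that are added to the RNA before labelling and belong to no mouse gene. All 24 of their probe sets were higher on the OX40L-Tg APC array, with a median difference of 0.57 and a range of 0.13 to 0.74, whereas the hybridisation controls, added after labelling, had a median of 0.10 over 18 probe sets. Among the 6378 probe sets above the floor that named no single gene and so entered no gene value, 64 were at least 2-fold higher and 48 at least 2-fold lower with OX40L-Tg APC. These 2 results were drawn from probe sets that enter no gene comparison of the report. The labelling controls were, however, labelled together with the mouse RNA. Whether their difference bears on the gene values was not tested.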

How the results depend on the processing

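All alternatives in this part were planned before the data were examined, and no shifted list turned its direction under any of them that gave it a value. Counts of 164 higher and 123 lower genes became 107 and 65 with the floor at the 75th percentile, 99 and 49 with an offset of 32 units, 406 and 354 at 1.5-fold, and 66 and 32 at 3-fold. The first of these settings tests fewer genes and the offset shrinks low values by construction. Under the other settings, which were the mean of probe sets, no shared probe sets, no floor, a floor from genes of other organs and 3 scalings, the counts lay between 146 and 164 higher and between 98 and 130 lower. Named genes were run under 4 settings. Of the 67 of at least 2-fold, none with a value turned its direction there, and 66 stayed past 2-fold after a lowess correction, 62 with the mean of probe sets, 50 with the offset, and 65 of the 65 with a value without shared probe sets.

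The median of the Th2 list was 1.57 with the floor at the 75th percentile, 1.60 with the floor from genes of other organs and 1.72 as a mean. That of the Th9-associated list was 0.77, 0.90 and 1.06 under the same settings. Among cell type lists, B cell markers moved from 0.23 to 0.44 and dendritic cell markers from 0.35 to 0.56 with the floor at the 75th percentile. Dendritic cell markers stood at 0.69 as a mean, and erythroid markers, at -0.39 in the main setting, at -0.13 with the offset and -0.67 as a mean. With the mean, Th1 and cytotoxic genes stood at -0.047 and coinhibitory receptors and costimulators at -0.025, and 7 of 22 shifted lists were no longer apart from random lists. These were the Th1, coinhibitory, cell cycle, glycolysis, anergy, cytokine receptor and p53 lists. Random lists not matched on level set 3 lists no longer apart, those of Treg, cell cycle and glycolysis genes, and quantile normalization did so for glycolysis alone. The cause was not tested for these. Of the lists not shifted, the floor at the 75th percentile set 4 apart, with Th17 genes at 0.69, Tfh genes at 0.22, TNF superfamily genes at -0.26 and interferon-stimulated genes at -0.26. The floor from genes of other organs set NK cell markers apart, at -1.77, and the mean set Tfh genes apart, at 0.54. Il21, at 5.79, weighs heavily on the mean of the Tfh list. Repressive chromatin modifiers were apart as lower under 3 settings, which were the mean of probe sets, quantile normalization and the floor from genes of other organs. Interferon-stimulated genes were apart as lower also under that floor and among random lists not matched on level. TNF superfamily genes were apart as higher after a lowess correction, at 0.09, opposite to their place under the 75th percentile floor. Genes of other organs were apart as higher with the mean of probe sets, at 0.17. Median and mean differed in sign for 5 lists, none of them shifted by the median, which were the Th17, Tfh, TNF superfamily, apoptosis and oxidative phosphorylation lists. No paired analysis was possible because each group holds 1 array, and for the same reason no array could be left out. Signal over background limits 48 of the higher and 52 of the lower genes, of which 8 and 13 had both values under the background level and the rest 1.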

Other observations

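All genes, families and tests in this part were chosen after the values were seen. Some single genes were picked from the 164 that were at least 2-fold higher with OX40L-Tg APC, and no group they belong to was tested. Penk, the precursor of the enkephalins, differed by 1.81. Nts, the precursor of neurotensin, read 20.4 units with Wt APC, under the background level, and 130 units with OX40L-Tg APC. Calcrl and Ramp3, whose products together form a receptor for adrenomedullin, differed by 2.46 and 1.41. Csf2, which encodes the cytokine GM-CSF, read 192 and 1503 units. Cysltr1, a receptor for cysteinyl leukotrienes, read 12.3 units and Il1r2, a decoy receptor for IL-1, 30.6 units with Wt APC, both under the background level, and 78.7 and 127 units with OX40L-Tg APC.

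Among 325 gene families that share the stem of their symbol, the guanylate-binding proteins (Gbp) had the largest median difference, at -1.01 over 6 members, between -1.05 and -1.01 under the 4 scalings tried. The Armcx genes, a cluster on the X chromosome, followed at 1.00 over 5 members, from 0.97 to 1.00 under those scalings, but only Armcx4, Armcx6 and Armcx3 were higher and Armcx2 read lower by -0.56, while Armcx5 was under the background level on both arrays. The Ifi family stood at -0.59 over 9 members, with Ifi203, Ifi205 and Ifi209 between -1.82 and -1.60, but Ifi27, Ifi35 and Ifi30 were higher by 0.55, 0.18 and 0.15. Single genes picked from the 123 that were at least 2-fold lower were Ipcef1 at -2.17, the phosphatase Ptpn22 at -1.36 and the interferon-regulated factor Irf8 at -1.22.

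Genes that differed by at least 2-fold in the same direction often lay next to each other on a chromosome. Among 10523 genes in order, 26 neighbouring pairs did so, against a highest of 14 and a median of 4 over 10000 shuffled orders, which argues against a random order. They include Septin8, Kif3a, Il4 and Il13 in a run on chromosome 11, Csf2 with Il3, Il2 with Il21, Acoxl with Bcl2l11, and Cmah with Ripor2. Pairs with related symbols numbered 14 without the probe sets marked as binding several transcripts, against a highest of 3 when shuffled, so those probe sets do not account for them. Pairs with unrelated symbols numbered 11, against a median of 4 and a highest of 13, and 0.15% of shuffled orders reached as many. Relatedness was judged by the spelling of the symbols alone, so Csf2 with Il3 counted as unrelated. The count of unrelated pairs did not pass every shuffled order, so it cannot decide on signal shared between related genes. For pairs with related symbols, shared regulation of neighbours cannot be told apart from such signal or from common ancestry of neighbouring genes. Whether any shared regulation follows from OX40L was not tested.

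Xist differed by 2.97 and 3.14 in its 2 probe sets above the floor, of 3 on the array, from a Wt APC value under the background level, which points to female RNA on the OX40L-Tg APC array as a hypothesis. A larger amount of the same APC is argued against, because the highest difference among 17 B cell and MHC class II genes was 1.00 and their median 0.25. Female cells throughout on that array are argued against, because the Y-linked genes Eif2s3y, Kdm5d and Uty read 832, 117 and 74.7 units there, all above the background level of 33.8 units. A share of female cells on that array only would dilute Y-linked transcripts, and 3 of 3 were lower with a median of -0.31. In its other probe set Kdm5d differed by only -0.04. The median lies at percentile 2.43 of random sets, too close to the limit of 2.5 to decide. Whether a share of the T cells, or the APC left among them, came from female mice in that condition alone is therefore open, and no biological explanation from the design was tested.

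The lower interferon-gamma-induced genes may follow from less interferon-gamma, since Ifng was lower too, at -0.83, on the same arrays. MHC class II genes had a median of 0.41 and B cell markers one of 0.23. Neither list was lower, as fewer APC with unchanged levels per cell would make them. The level of these transcripts per APC was not measured and can change, so fewer APC on the OX40L-Tg APC array remain possible. The deposited arrays were already equalised, with sorted log2 values at most 0.07 apart, so a further scaling could move the list little. The list stood at -0.70 after a lowess correction and stayed below all random lists. An effect of the equalisation itself was not tested. A direct action of OX40L on the response to interferon-gamma, the type 2 cytokines and a difference between the 2 cultures by chance remain open.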
